A study of Danio rerio with 58 samples.

How the data were processed

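Single cells of the dorsal aorta of zebrafish embryos carrying 2 flk1 reporters were picked by hand as red Eos+ cells, and each was made into 1 Smart-seq2 library from polyA RNA captured with oligo-dT and sequenced as 150 bp paired-end reads, per the labels' protocols. The 58 cells were grouped by the region and stage that the labels give, as 18 roof and 18 floor cells at 21 hpf and 10 roof and 12 floor cells at 28 hpf. The authors deposited gene counts for each cell. Per the submitters' processing notes, reads were trimmed with Trim Galore and aligned with STAR to the GRCz11 assembly (danRer11). The versions of these tools, the counting tool, the annotation and the strand setting are not given in the sources used here. No cell of the files was without a label.

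The table had 35117 genes, of which 14082 had no read in any cell. Of the gene IDs, 4704 were given a symbol from a table of gene IDs and symbols, and where 2383 entries shared a symbol, the entry with the most reads kept it. Total counts per cell ranged from 129849 to 8254178.

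Every cell was thinned to 200000 reads without replacement (seed 1), the largest of 5 depths that kept at least 90% of the cells of each group, which left out 1 roof cell of 21 hpf. The thinned counts of a group were summed, to 3400000 and 3600000 reads in the roof and floor at 21 hpf and 2000000 and 2400000 at 28 hpf, and divided by their total. A ratio was the log2 ratio of 2 such levels. With a group at 0 reads, its level was set to 3 reads, equal to 0.8824, 0.8333, 1.5 and 1.25 CPM in the 4 sums, and the ratio was given as a bound. Such a bound, written as at least, does not cover the counting error of the other group, which matters most at low counts. Intervals of levels and ratios were exact 95% intervals for the counting of reads, and those of shares were for the counting of cells. Animals were not named and each group therefore held 1 sample, so no p-value, standard error or number of changed genes was computed from the cells. A gene was detected in a cell with 5 or more thinned reads, and unthinned shares were given beside thinned ones.

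The 4 comparisons were floor against roof at 21 hpf and at 28 hpf, and 28 against 21 hpf in the roof and in the floor. The groups, the comparisons, the thinning, the 18 key genes, the 2 leading lists and most alternatives were chosen before the data were examined. The 23 gene lists were written from general knowledge of the genes. They cover hemogenic, arterial and Notch, venous, pan-endothelial, sprouting and tip-cell, BMP target, Hedgehog target, flow-responsive, transition and adhesion, inflammatory, S-phase, mitosis, glycolysis, and early-response and stress genes. Others hold markers of erythroid, myeloid, muscle, neural, notochord and sclerotome, epidermis, pronephros, mural and mesenchyme, and endoderm and gut cells. They held 415 entries of 406 genes, and 399 of these genes were in the table. A member needed 10 or more thinned reads over both groups, and members with a group at 0 reads entered at their bound, so the median was itself a bound where such members could move it. The median of a list was placed among the medians of 10000 random lists of equal size drawn from 20 bins of expression.

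Genes were named by a rule. Up to 12 genes higher and 12 lower in each comparison were taken by ratio if the higher group had 50 or more CPM and 5 or more reads in at least 1 of 3 of its cells. The ratio also had to be at least 2-fold from thinned sums, raw sums and mean per-cell levels, and to stay at 2-fold and move by no more than 1.5 times when any 1 cell was left out. Key genes were given whatever their values, and list examples were the members with the largest ratios each way at 50 or more CPM. The key genes were runx1, gata2b, gfi1aa, myb, itga2b, kita, tal1, lmo2, dll4, efnb2a, hey2, notch1b, cldn5b, flt4, stab2, kdrl, cdh5 and klf2a.

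Alternatives were raw sums, mean per-cell levels, another seed, TMM factors of edgeR 4.0.16, size factors of DESeq2 1.42.0, totals without mitochondrially encoded genes, other read minimums, a pseudocount of 1 CPM, and leaving out cells with under 2000 genes, each cell in turn or cells that share a title part at 28 hpf. Leaving out 12 cells with over 1% erythroid or muscle counts was added after seeing the data, as was leaving out the 4 floor cells of 21 hpf whose pan-endothelial share reached that of the lowest roof cell. Of the 6 cells of title part M12, 1 is titled D12 and described as M12. The steps were tested on simulated data, in which 100 of 35117 genes given a 2-fold difference had median log2 ratios of 0.913 to 0.934 over the 4 comparisons, where 0.915 to 0.930 was set. Lists planted at 2-fold lay above all random lists, and 0 to 2 of 40 unchanged lists lay outside the central 95% of them. All simulated cells were drawn from the mean profile of 1 group. These rates therefore do not cover the spread between real cells or genes that vary together. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3.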

Results

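Single cells of the dorsal aorta of zebrafish embryos were compared between the roof and the floor of the vessel at 21 and 28 hours post fertilization (hpf). The embryos carried a green reporter and a nuclear Eos reporter of the flk1 gene, which is also called kdrl, and cells with photoconverted red Eos were picked by hand. Each picked cell was 1 library of the Smart-seq2 protocol, sequenced as 150 bp paired-end reads. The data comprised 18 roof cells and 18 floor cells at 21 hpf, and 10 roof cells and 12 floor cells at 28 hpf. Embryos were not named in the sources used here, so each group counted as 1 sample and no test across cells was made.

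Total counts per cell ranged from 129849 to 8254178. The median was 1744000 in the roof (129849 to 4693992) and 1448000 in the floor (216581 to 4227288) at 21 hpf. At 28 hpf it was 4242000 in the roof (3630613 to 5574794) and 5044000 in the floor (4339995 to 8254178). Before reads were summed, every cell was thinned to 200000 reads, which left out 1 roof cell of 21 hpf with 129849 counts. At that depth the median cell had reads in 4750 and 5942 genes in the roof and floor at 21 hpf, and in 4622 and 5186 genes at 28 hpf. Mitochondrially encoded genes took a median of 2.12%, 2.27%, 2.34% and 2.18% of the counts in the same 4 groups. Levels are given in CPM of the summed reads of a group. Their 95% intervals are exact Poisson intervals, those of ratios are exact binomial intervals and those of shares are Clopper-Pearson intervals. Those of levels and ratios cover the counting of reads only, not the spread between cells or embryos. Those of shares cover the counting of cells as if each were drawn independently, not the spread between embryos.

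Endothelial and erythroid genes divided the roof cells from most floor cells. Pan-endothelial genes, such as kdrl and cdh5, made up a median of 2.24% of the counts of a roof cell and 0.157% of a floor cell at 21 hpf. At 28 hpf the medians were 1.98% and 0.0940%. Erythroid genes, such as the embryonic globins, had medians of 0.00690% in the roof and 0.573% in the floor at 21 hpf, and of 0.00340% and 0.199% at 28 hpf.

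More than 1% of the counts fell on erythroid genes in 8 of 18 floor cells at 21 hpf (44.4%, interval 21.5% to 69.2%) and in 3 of 12 at 28 hpf (25%, 5.49% to 57.2%). None of the roof cells passed that level. The Clopper-Pearson interval of 0 of 18 at 21 hpf reached up to 18.5%, and that of 0 of 10 at 28 hpf up to 30.9%. By the simpler limit of 3 divided by the number of cells, these were 16.7% and 30.0%. Pan-endothelial genes exceeded 1% of the counts in 17 of 18 roof cells (94.4%) and 3 of 18 floor cells (16.7%, 3.58% to 41.4%) at 21 hpf. At 28 hpf they did so in 10 of 10 roof cells and 0 of 12 floor cells, the latter with an interval up to 26.5% (25% by 3 divided by the number of cells). Floor cells 3, 6, 16 and 18 of 21 hpf had pan-endothelial shares of 0.845% to 3.69%, above the lowest roof cell (0.504%), and erythroid shares of up to 0.0146%, below the highest roof cell (0.0179%). The other 14 floor cells of 21 hpf had pan-endothelial shares of up to 0.305%. At 28 hpf the highest floor cell had 0.330% and the lowest roof cell 1.09%. Muscle genes took 8.46% of the counts of floor cell 6 at 28 hpf and no more than 0.0438% in any roof cell of that stage.

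**Figure D1:**
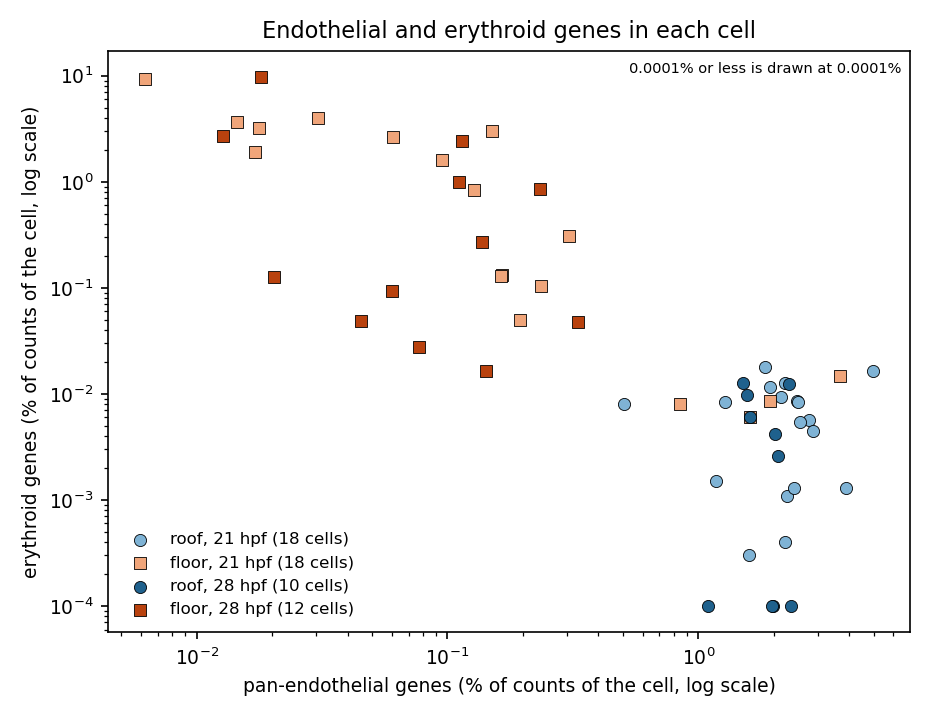
Each point is 1 of the 58 cells, placed by the percentage of its counts in pan-endothelial genes and in erythroid genes, both on log axes, with colour and shape by group. Most floor cells lie at the upper left, and the 10 roof cells of 28 hpf lie at or above 1.09% on the pan-endothelial axis.

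At 21 hpf, genes of blood formation were higher in the floor and genes of the endothelium were higher in the roof. The heme synthesis gene alas2 reached 666 CPM (639 to 693) in the floor and 0.882 (0.182 to 2.58) in the roof, higher by 755-fold (258 to 3662). The transcription factor gene gfi1aa stood at 677 (650 to 704) in the floor and 9.71 (6.68 to 13.6) in the roof. The vascular endothelial growth factor receptor gene kdrl was lower in the floor by 4.61-fold (4.50 to 4.73), at 2212 (2160 to 2260) against 10200 (10100 to 10300), by 10.2-fold without floor cell 6 and by 53-fold without floor cells 3, 6, 16 and 18. The flow-induced transcription factor gene klf2a had 53.8 CPM (46.3 to 62.2) in the roof and 0 in the floor, lower by at least 64.6-fold.

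Genes are named below by ratio only if they also passed the filters on level, share of cells and leaving out 1 cell, so some genes with larger ratios are not among them. Of the 12 such genes higher in the floor at 21 hpf, 6 were in the erythroid list, namely alas2, hbae3, slc4a1a, epb41b, gata1a and hbbe2. The embryonic globin gene hbae3 was higher by 587-fold (343 to 1102), at 2242 against 3.82 CPM. It had 1068 to 13245 CPM in the 8 floor cells of over 1% erythroid counts and 0 to 95.8 in the other floor cells. The red cell anion exchanger gene slc4a1a, at 362.5 against 0, was higher by at least 411-fold. The mitochondrial transporter gene abcb10 was higher by at least 230.1-fold, aff2 by 228-fold (104 to 621), the membrane skeleton gene epb41b by at least 225-fold and hbz by at least 214-fold. For gata1a, the transcription factor of red cell formation, the floor had 165 CPM and the roof 0, higher by at least 187-fold. The 8 floor cells of over 1% erythroid counts had 189 to 822 CPM of gata1a, and the other floor cells 0 to 113. The remaining genes were nt5c2l1, the globin gene hbbe2, rap1gap2a and acss1, higher by at least 169.7-fold, 130.3-fold, 123-fold and 119-fold.

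Among the genes lower in the floor at 21 hpf that passed the filters, the coronin gene coro1cb was lower by 189.9-fold (64.6 to 924) and the formin gene daam1a by 157-fold (53.4 to 765). For the retinoid-binding gene rbp7b, with 79.4 CPM in the roof and 0 in the floor, the difference was at least 95.3-fold. The genes skib, ergic1 and abtb2b were lower by 56.9-fold (21.9 to 211), 53.2-fold (20.5 to 197) and 32.3-fold (14.6 to 89.2). The phosphatase gene dusp1 was lower by 11.7-fold (9.84 to 14), or 17.9-fold without the 4 cells of roof-like pan-endothelial share, and the transforming growth factor receptor gene tgfbr2b by 15-fold (11.6 to 19.8). The ratios of agpat4, dync1li2 and prex1 were 16.6-fold (9.66 to 30.8), 14-fold (11 to 18.2) and 13.8-fold (8.44 to 24.2) in the same direction.

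Among the blood regulators chosen beforehand, gfi1aa was higher in the floor at 21 hpf by 69.8-fold (49.5 to 102), and by 433-fold without roof cell 7. It had 5 or more thinned reads in 15 of 18 floor cells and 1 of 17 roof cells, and 5 or more unthinned reads in 16 of 18 and 2 of 18. The level of myb was higher by 8.72-fold (7.67 to 9.94), at 669 against 76.8 CPM, by 21.0-fold without roof cell 10 and by 13.4-fold without roof cell 7. It was detected in 14 of 18 floor cells and 2 of 17 roof cells (14 of 18 and 4 of 18 unthinned). The hemogenic regulator gene runx1 had 4.72 CPM (2.75 to 7.56) in the floor and 0 in the roof, higher by at least 5.35-fold, and by at least 2.33-fold without floor cell 5. Unthinned runx1 reads reached 5 in 5 of 18 floor cells and 0 of 18 roof cells, and thinned reads in 1 of 18 and 0 of 17. The floor level of gata2b, 15.6 CPM, was higher by 3.31-fold (1.87 to 6.17), and by 5.53-fold without roof cell 8. The stem cell regulators tal1 and lmo2 were higher by 1.94-fold (1.78 to 2.11) and 1.18-fold (1.11 to 1.25). The genes itga2b and kita had 3 or fewer reads in each group at 21 hpf, so no ratio was taken.

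Arterial and venous genes chosen beforehand were lower in the floor at 21 hpf. The Notch ligand gene dll4 was lower by 4.88-fold (4.57 to 5.21) and by 8.295-fold without floor cell 3, and efnb2a was lower by 3.62-fold (3.33 to 3.95). The Notch pathway genes hey2 and notch1b were lower by 2.68-fold (2.49 to 2.88) and 2.06-fold (1.91 to 2.21), the latter by 3.91-fold without floor cell 16. The tight junction gene cldn5b was lower by 2.88-fold (2.68 to 3.10) and the lymphatic and venous receptor gene flt4 by 4.26-fold (3.61 to 5.05). Without floor cell 3 these ratios were 8.53-fold and 10.9-fold. The scavenger receptor gene stab2 was lower by 3.27-fold (2.94 to 3.63) and the adherens junction gene cdh5 by 5.43-fold (4.98 to 5.92). At least 5 thinned reads of kdrl were found in 14 of 18 floor cells and 17 of 17 roof cells, and of cdh5 in 6 of 18 and 15 of 17. The floor sum owed much of these genes to the 4 cells of roof-like pan-endothelial share. As kdrl and cdh5 belong to the list that picked these 4 cells, their larger difference without them follows in part from the choice. Without these 4 cells, left out after the values were seen, dll4 was lower by 16.5-fold, efnb2a by 53.2-fold, notch1b by 12.5-fold, stab2 by 10.4-fold, kdrl by 53-fold and cdh5 by 72-fold, and cldn5b and flt4, with fewer than 5 floor reads left each, by about 555-fold and 291-fold. The median floor cell had 0.946 CPM of cldn5b, 15 of dll4 and 6.18 of cdh5, and the median roof cell 719, 1426 and 890. Another removal chosen after the values were seen moved the other way. Without the 8 floor cells of over 1% erythroid counts, the pan-endothelial log2 median was -1.32 in place of -2.15. Those 8 cells had at most 373 CPM of kdrl and 2.28 of dll4. At least 5 unthinned reads of kdrl were found in 17 of 18 floor cells and 18 of 18 roof cells, and of cdh5 in 10 of 18 and 16 of 18.

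**Figure D2:**
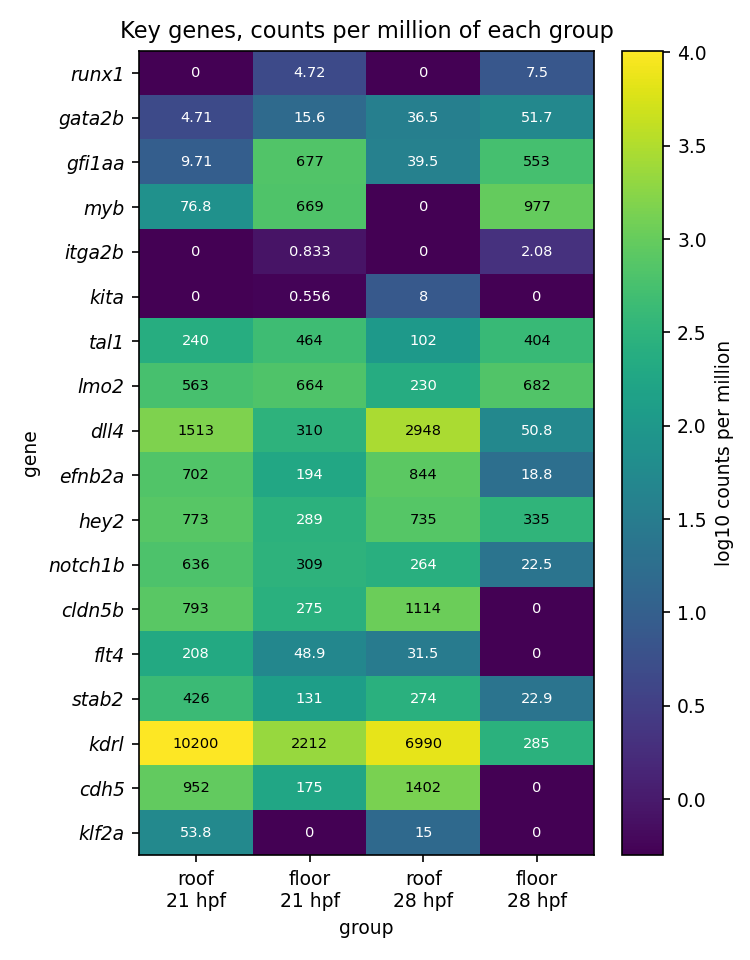
The colour and the printed number give the CPM of each of the 18 key genes in the thinned sums of the 4 groups, with a log10 colour scale. The gene myb reads 669 and 977 in the floor, and cdh5 reads 952 and 1402 in the roof at 21 and 28 hpf.

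As a list, hemogenic genes were higher in the floor at 21 hpf by a median of at least 3.28-fold (log2 1.71), above 99.99% of 10000 random lists matched on expression. The median gene, cebpa, is also in the myeloid list and is the median gene there, and spi1b and lcp1 are in both lists. The higher median therefore does not set hemogenic cells apart from other blood cells. Of the 25 measured hemogenic genes, 15 were higher by at least 2-fold, 6 were lower and 4 lay within 2-fold. Here gfi1b was higher by at least 85.6-fold, and gata2a was lower by 5.51-fold (4.71 to 6.48). The arterial and Notch list was lower by a median of 2.88-fold (log2 -1.53), below all 10000 random lists, with 4 genes higher, 18 lower and 5 within 2-fold of 27. The Notch target gene hey1 was lower by 16.6-fold (13.7 to 20.2) and sox7 by 6.11-fold (5.58 to 6.69). These were 54.1-fold without floor cell 3 and 12.6-fold without floor cell 16. The arterial and Notch median was lower by 16.5-fold without the 4 floor cells of roof-like pan-endothelial share. Without the 8 floor cells of 21 hpf with over 1% erythroid counts, left out after the values were seen, the hemogenic median was higher by at least 5.21-fold and the arterial and Notch median lower by 1.71-fold.

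Other endothelial lists at 21 hpf were lower in the floor as well. The pan-endothelial median was lower by 4.42-fold, below all random lists, with 16 of 20 genes lower and 4 within 2-fold. Its regulator gene etv2 was lower by 51.9-fold (42.8 to 63.6), by 87.3-fold without floor cell 6 and by 81.8-fold without floor cell 3, whereas the angiopoietin receptor gene tek was higher by 1.07-fold (0.926 to 1.24). The venous list was lower by 2.91-fold at the 0.3 percentile (2 higher, 8 lower and 1 within 2-fold of 11), and nr2f2 by at least 74.8-fold, or at least 25.9-fold without roof cell 11. Sprouting and tip-cell genes were lower by 1.82-fold at the 2.6 percentile (3, 7 and 5 of 15), by 4.09-fold without floor cell 3 and by 3.30-fold without floor cell 16. Their gene esm1 was lower by 18.7-fold (14.8 to 24), or 51.0-fold without floor cell 16. Without the 4 floor cells of roof-like pan-endothelial share, the pan-endothelial median was lower by 51.2-fold, the venous by 48.6-fold and the sprouting median by 14.5-fold. As these cells were picked by their pan-endothelial share and no roof cell was left out, the larger differences follow in part from the choice.

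Among the pathway lists at 21 hpf, BMP targets were lower in the floor by 2.72-fold at the 1.38 percentile (6 lower and 3 within 2-fold of 9), with id3 lower by 3.18-fold (2.80 to 3.63). Flow-responsive genes were lower by 2.82-fold at the 0.555 percentile (1, 6 and 4 of 11), by 4.57-fold without floor cell 5 and by 1.59-fold without roof cell 4, and piezo1 by 1.17-fold (0.970 to 1.40). The list of transition and adhesion genes was lower by 2.22-fold at the 0.82 percentile (3, 11 and 2 of 16), with zeb2a at 1.06-fold (0.918 to 1.22). Early-response and stress genes were lower by 1.93-fold at the 0.97 percentile (1, 10 and 11 of 22), and fosab by 1.38-fold (1.25 to 1.51). For mitosis genes the median was lower by 1.73-fold at the 2.94 percentile (1, 6 and 15 of 22), with aurka lower by 3.96-fold (3.51 to 4.48) and bub1 higher by 3.29-fold (2.56 to 4.26).

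Medians near those of random lists were found for 4 lists at 21 hpf. S-phase genes were higher by 1.13-fold (84.3 percentile), with mcm3 higher by 3.82-fold (3.39 to 4.30). Inflammatory genes were higher by 1.09-fold (45.9 percentile), or 1.64-fold without roof cell 12, with stat3 higher by 1.83-fold (1.43 to 2.36) and stat1a lower by 2.79-fold (2.18 to 3.60). Glycolysis genes were lower by 1.13-fold (33.4 percentile), with pgk1 higher by 2.90-fold (2.38 to 3.55) and gapdhs lower by 2.34-fold (1.98 to 2.76). The 4 measured Hedgehog targets were lower by 1.70-fold (18.2 percentile), and gli2a by 1.60-fold (1.38 to 1.86), or 2.59-fold without floor cell 3.

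Marker lists of other cell types at 21 hpf differed in both directions. Erythroid genes were higher in the floor by a median of at least 411-fold, or at least 263-fold without roof cell 10, above all random lists and in 21 of 21 genes, with the receptor gene epor higher by at least 107.7-fold and urod by 28.0-fold (23.7 to 33.2). Myeloid genes were higher by 3.28-fold (96.2 percentile, 4 higher and 2 lower of 7), by 5.32-fold without roof cell 4 or 6, 5.36-fold without roof cell 14 and 6.69-fold without roof cell 10. Among them was the myeloperoxidase gene mpx at 453 CPM in the floor, from 5 of 18 cells, and 0 in the roof. These 5, floor cells 7, 10, 13, 15 and 17, were all cells of over 1% erythroid counts. The muscle, notochord and sclerotome, and mural lists had medians lower in the floor by at least 5.19-fold, at least 3.88-fold and 5.79-fold over 4, 5 and 3 measured genes, and the notochord and sclerotome median by at least 6.0-fold without floor cell 6. The neural median of 6 genes was log2 0.13, was -1.58 without floor cell 9 or 14 and -1.60 without floor cell 11, and was 1.83 without roof cell 14. The pronephros median was higher by at least 4.90-fold over 2 genes and the endoderm median by at least 6.93-fold over 3. Of the epidermis list only the keratin gene krt8 was measured, lower by 1.63-fold (1.56 to 1.71), or by 4.48-fold without floor cell 3.

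Other choices moved some list medians at 21 hpf by over 1.5 times. Without the cells of over 1% erythroid or muscle counts, chosen after the values were seen, the log2 median was -1.32 for pan-endothelial, -0.93 for venous, -0.73 for BMP target, -1.41 for mitosis, 5.08 for erythroid, -0.90 for neural and -1.11 for notochord and sclerotome genes. With raw sums it was 2.70 for hemogenic, -2.18 for venous, 11.1 for erythroid, 2.70 for myeloid, 1.92 for neural and -2.99 for notochord and sclerotome genes. A minimum of 100 reads gave -1.56 for sprouting, -2.07 for transition and adhesion, 0.90 for inflammatory, 1.02 for myeloid and -2.02 for neural genes. Another seed gave 2.52 for myeloid and 1.66 for neural genes, and no minimum gave 1.02 for myeloid genes. The erythroid median was 9.66 with mean per-cell levels and 7.64 with a pseudocount.

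At 28 hpf the floor sum had no read of several endothelial genes, and the roof sum had none of several blood genes. The zinc finger gene blf reached 5772 CPM (5680 to 5870) in the floor, with 5 or more reads in 12 of 12 cells, and 0 in the roof, higher by at least 3848-fold. The gene myb stood at 977 (938 to 1020) against 0, higher by at least 651-fold, and was detected in 11 of 12 floor cells and 0 of 10 roof cells (12 of 12 and 0 of 10 unthinned). The adherens junction gene cdh5 was lower in the floor by at least 1122-fold, at 0 against 1402 (1350 to 1450) CPM. Dll4 was lower by 58.0-fold (48.5 to 70.0), at 50.8 (42.2 to 60.7) against 2948 (2870 to 3020), or by 109.9-fold without floor cell 1.

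Of the 12 genes higher in the floor at 28 hpf that passed the filters, myb and ikzf1 were in the hemogenic list and cahz in the erythroid list. The zinc finger gene znfl2a was higher by at least 705-fold and the lymphoid regulator gene ikzf1, at 266 against 0 CPM, by at least 177-fold. The genes hdr, tdh and the carbonic anhydrase gene cahz were higher by at least 369-fold, 295-fold and 290.3-fold. For the thioredoxin gene txn the bound was 216-fold, for the parvin gene parvg 212-fold, for lpar5a 202-fold, for the kindlin gene fermt3b 182-fold and for the amino acid transporter gene slc38a5a 177-fold.

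Of the 12 genes lower in the floor at 28 hpf that passed the filters, clec14a, cdh5 and flt1 were in the pan-endothelial list and cxcr4a and cldn5b in the arterial and Notch list. The Notch target genes her15.1 and her15.2, at 2821 and 1488 CPM in the roof and 0 in the floor, were lower by at least 2257-fold and 1190-fold, and her2 by at least 674-fold. The water channel gene aqp1a.1 was lower by 1289-fold (441 to 6255). At least 1172-fold separated the regions for oaz2a, 1147-fold for the endothelial lectin gene clec14a and 1108-fold for the chemokine receptor gene cxcr4a. The junction gene cldn5b was lower by at least 891-fold, the tip-cell gene esm1 by at least 812-fold, the collagen chaperone gene serpinh1b by at least 794-fold and the growth factor receptor gene flt1 by at least 767-fold.

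Of the remaining key genes, gfi1aa was higher in the floor at 28 hpf by 14-fold (11.2 to 17.8), by 28.4-fold without roof cell 5 and by 8.21-fold without floor cell 9. It was detected in 9 of 12 floor cells and 3 of 10 roof cells (10 of 12 and 3 of 10 unthinned). The levels of tal1 and lmo2 were higher by 3.98-fold (3.42 to 4.65) and 2.97-fold (2.67 to 3.30), the former by 9.20-fold without roof cell 2. Runx1 had 7.50 CPM (4.44 to 11.9) in the floor and 0 in the roof, higher by at least 5.00-fold. Its unthinned reads reached 5 in 8 of 12 floor cells and 2 of 10 roof cells, and its thinned reads in 1 of 12 and 0 of 10. The ratio of gata2b was 1.42-fold (1.05 to 1.92) higher, 2.66-fold without roof cell 2 and lower by 1.36-fold without floor cell 9. The receptor gene kita had 8.00 CPM in the roof and 0 in the floor, lower by at least 6.4-fold. The platelet and stem cell integrin gene itga2b had 5 reads in the floor sum and 0 in the roof sum, too few for a ratio.

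Kdrl was lower in the floor at 28 hpf by 24.6-fold (22.7 to 26.6), at 285 (264 to 307) against 6990 (6870 to 7110), and by 43.6-fold without floor cell 1. It was detected in 5 of 12 floor cells and 10 of 10 roof cells (9 of 12 and 10 of 10 unthinned). Efnb2a was lower by 45.0-fold (33.5 to 61.9), or 92.8-fold without floor cell 3, and notch1b by 11.7-fold (8.86 to 15.8), or 29.0-fold without floor cell 7. The ratio of hey2 was 2.19-fold (2.01 to 2.39) lower, or 10.3-fold without floor cell 4. Stab2 was lower by 12-fold (9.05 to 16.1), by 23.2-fold without floor cell 6 and by 7.39-fold without roof cell 6. The roof levels of flt4 and klf2a, 31.5 and 15 CPM against 0, gave bounds of 25.2-fold and 12-fold lower. These bounds were 9.78-fold without roof cell 10 and 4.89-fold without roof cell 3.

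The hemogenic list was higher in the floor at 28 hpf by a median of at least 3.98-fold (log2 1.99), above 99.98% of the random lists, with 16 genes higher, 5 lower and 4 within 2-fold of 25. Its gene mecom ran the other way, lower by at least 57.2-fold. Arterial and Notch genes were lower by a median of at least 23.2-fold (log2 -4.53), below all random lists, with 2 genes higher, 23 lower and 2 within 2-fold of 27. It was lower by at least 37.6-fold without floor cell 1, 53.2-fold without floor cell 11 and 44.9-fold without roof cell 1. Of the 2 genes that were higher, hes6 differed by 11.5-fold (7.12 to 19.7), or 62.0-fold without roof cell 2. The pan-endothelial median was lower by at least 170.2-fold, or at least 256-fold without floor cell 9, below all random lists, with 19 of 20 genes lower. Its exception, the transcription factor gene fli1a, was lower by 1.85-fold (1.75 to 1.97) and was detected in 12 of 12 floor cells and 10 of 10 roof cells.

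Further lists lower in the floor at 28 hpf were the venous list by at least 16.4-fold (0.035 percentile, 1 higher and 10 lower of 11), or at least 9.94-fold without roof cell 10, and the sprouting list by at least 47.3-fold (below all random lists, 14 lower of 15). The venous gene stab1 was lower by at least 142-fold. The 3 measured Hedgehog targets were lower by at least 42.0-fold (0.255 percentile), with gli2a lower by at least 96.4-fold. Flow-responsive genes were lower by at least 21.1-fold (0.025 percentile, 1, 9 and 1 of 11), and klf6a by 5.09-fold (4.31 to 6.02), or 8.17-fold without floor cell 1. Early-response and stress genes were lower by 3.78-fold (0.02 percentile, 1, 17 and 4 of 22), although ier2a stood at 1.01-fold (0.928 to 1.09). BMP targets were lower by 3.93-fold (3.09 percentile, 1, 5 and 2 of 8), by 6.70-fold without floor cell 1 and by 1.09-fold without the 5 cells of title part 3 of the roof, with smad6b lower by at least 60.4-fold. Transition and adhesion genes were lower by 3.84-fold (4.68 percentile, 2, 9 and 2 of 13), by 9.53-fold without floor cell 1 or 4, 6.99-fold without floor cell 2, 5.79-fold without floor cell 3 and 5.99-fold without floor cell 6, with snai1a lower by at least 73.6-fold and zeb2a at 1.05-fold (0.870 to 1.27).

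S-phase genes were higher in the floor at 28 hpf by a median of at least 11.1-fold, above all random lists and in 19 of 19 genes. The median was at least 17.8-fold without roof cell 10, and 4.68-fold without the cells of over 1% erythroid or muscle counts. The replication helicase gene mcm2, at 271 against 0 CPM, was higher by at least 181-fold, or at least 119-fold without floor cell 6, and pcna by 3.48-fold (2.96 to 4.1). Mitosis genes were higher by 1.78-fold (90.6 percentile, 7, 2 and 13 of 22), by 2.92-fold without roof cell 9 and by 3.02-fold without roof cell 10. The mitosis median was higher by 1.07-fold without the 4 cells of title part 2 of the roof and by 33.7-fold without the 5 of part 3. The cyclin gene ccna2 was higher by 3.51-fold (2.90 to 4.28), or 9.07-fold without roof cell 10, and kif11 was lower by 2.29-fold (1.94 to 2.71), or higher by 2.41-fold without that cell. Glycolysis genes were higher by 1.73-fold (87.9 percentile, 7, 4 and 8 of 19), with aldoab counted in 1 of 12 floor cells and gapdhs lower by 2.44-fold (2.26 to 2.63), or 3.74-fold without floor cell 1. Inflammatory genes were lower by 1.35-fold (26.4 percentile, 4, 7 and 4 of 15), with irf1b higher by 4.74-fold (2.99 to 7.83).

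Of the marker lists of other cell types, erythroid genes were higher in the floor at 28 hpf by a median of at least 124-fold, in 21 of 21 genes. The globin gene hbbe1.1 was higher by at least 2191-fold, or at least 840.3-fold without floor cell 11. Myeloid genes were higher by at least 12.1-fold (99.8 percentile, 4 higher and 1 lower of 6), with mpx higher by at least 92.2-fold, or at least 36.4-fold without floor cell 11, and srgn lower by 7.51-fold (5.41 to 10.7). Reads of mpx were counted only in floor cells 5, 10 and 11, each with over 1% erythroid counts. The muscle median was higher by at least 155-fold over 16 genes, with mylpfa and tpma counted in 1 of 12 floor cells, and without floor cell 6 the log2 median was -3.41. Epidermis genes were higher by at least 8.33-fold over 5 genes, whereas krt8, at 95.8 against 5310 CPM, was lower by 55.4-fold (48.6 to 63.4), or 272-fold without floor cell 1. The neural and the notochord and sclerotome lists were lower by at least 83.8-fold and at least 18-fold over 2 and 3 genes, and the pronephros list by at most 5.37-fold over 2. The 2 measured mural genes each had 0 reads in a different region, and 1 endoderm gene was higher by 10.2-fold. The titles of the roof and floor cells took different forms at 28 hpf, so region and collection series cannot be told apart at that stage.

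Other choices moved list medians at 28 hpf by over 1.5 times as well. Without the cells of over 1% erythroid or muscle counts the log2 median was -5.85 for arterial and Notch, -6.83 for pan-endothelial, -4.98 for sprouting, -1.39 for BMP target, -3.82 for flow-responsive, 0.15 for inflammatory, 2.23 for S-phase, 5.45 for erythroid, -2.95 for muscle and 3.64 for epidermis genes. With raw sums it was -6.15 for arterial and Notch, -9.99 for pan-endothelial, -5.23 for flow-responsive, 4.93 for S-phase, 11.3 for erythroid, 5.69 for myeloid, 10.4 for muscle and 7.37 for epidermis genes. A minimum of 100 reads gave 1.34 for hemogenic, -5.53 for arterial and Notch, -6.15 for sprouting, -0.94 for BMP target, -3.70 for flow-responsive, -3.87 for transition and adhesion, 0.16 for inflammatory, 4.61 for S-phase, 2.28 for myeloid and -5.79 for epidermis genes. Without title part 3 of the roof the values were -1.74 for venous, 2.93 for myeloid, 6.28 for muscle and 2.06 for epidermis genes, and without part 2 they were 6.21 for erythroid, 6.54 for muscle and 2.32 for epidermis genes. Without title part M12 of the floor, which takes in 1 cell titled D12 but described as M12, they were -3.07 for venous, 0.50 for inflammatory, 0.23 for mitosis, 1.54 for glycolysis, 6.36 for erythroid, 8.28 for muscle and 4.06 for epidermis genes. Without M8 they were -2.87 for BMP target, -3.25 for transition and adhesion and 2.90 for myeloid genes, and without M9 -3.25 for transition and adhesion genes. Another seed gave -5.02 for flow-responsive, 4.08 for S-phase and 2.47 for epidermis genes. Mean per-cell levels gave -5.10 for flow-responsive and 7.59 for erythroid genes, a pseudocount 7.54 for erythroid genes, and leaving out cells with under 2000 genes -7.999 for pan-endothelial genes.

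Between the regions, the ratios at 28 and at 21 hpf were correlated across 4899 genes with 50 or more CPM in a group (Pearson r 0.636, Spearman 0.636). With a minimum of 10 CPM (9423 genes) the values were lower, at 0.515 and 0.495. Among genes of 200 or more CPM (1382 genes) the values were 0.720 and 0.743. From 21 to 28 hpf the log2 region ratio of the median pan-endothelial gene was lower by at least 5.17, and that of the median arterial and Notch gene by at least 3.22. For S-phase genes it was higher by at least 3.94. The first 2 of these rest in part on the 4 floor cells of 21 hpf with a roof-like pan-endothelial share, without which the pan-endothelial log2 median at 21 hpf was -5.68 and the arterial and Notch median -4.04, against -7.41 and -4.53 at 28 hpf.

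**Figure D3:**
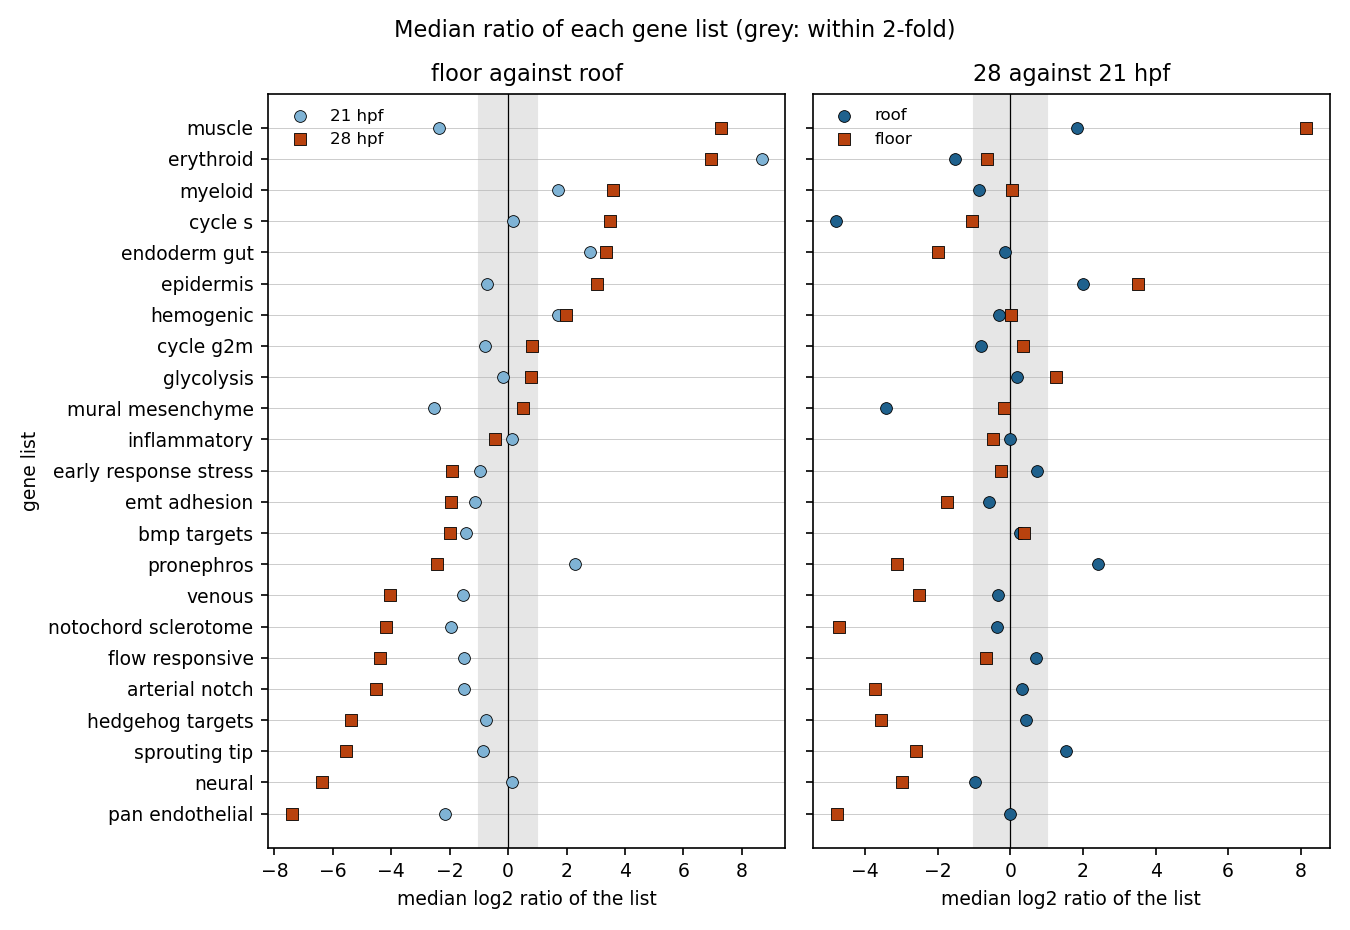
Points give the median log2 ratio of each of the 23 gene lists, on the left for floor against roof at 21 and 28 hpf and on the right for 28 against 21 hpf in roof and floor, with the range within 2-fold in grey. The erythroid list lies at 8.68 and 6.95 on the left, and the pan-endothelial list at -2.15 and -7.41.

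Within the roof, genes of DNA replication were lower at 28 than at 21 hpf, while several Notch and sprouting genes were higher. The helicase gene mcm6 had 171 CPM (157 to 185) at 21 hpf, with 5 or more reads in 13 of 17 cells, and 0 at 28 hpf, lower by at least 114-fold. The Notch target gene her15.1 was higher at 28 hpf by 9.80-fold (9.15 to 10.5), at 2821 (2750 to 2900) against 288 (270 to 307). The chemokine receptor gene cxcr4a was higher by 81.2-fold (62.6 to 107), at 1384 (1330 to 1440) against 17.1 (13 to 22.1), and by 158-fold without roof cell 3 of 21 hpf. The levels of kdrl were nearer, lower at 28 hpf by 1.46-fold (1.43 to 1.49).

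Genes higher at 28 hpf in the roof that passed the filters included gpm6ab, at 201.5 against 0 CPM and at least 228-fold, and the LIM domain gene fhl2a, at least 105-fold. The gene dnase1l1 was higher by at least 81.0-fold, the death ligand gene tnfsf10 by at least 75.9-fold and the epiplakin gene eppk1 by at least 60.1-fold. The myosin light chain gene myl9a was higher by 20.01-fold (14.7 to 27.9) and the Notch target gene her12 by 19.4-fold (15.7 to 24.2). For carhsp1, notchl, dennd4a and the G protein gene gng10 the ratios were 18.5-fold (11.2 to 32.4), 11.4-fold (9.06 to 14.5), 10.8-fold (7.37 to 16.3) and 10.7-fold (7.33 to 16).

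Of the 12 genes lower at 28 hpf in the roof that passed the filters, mcm6, mcm2, cdc45 and mcm3 were in the S-phase list. The genes mcm2, cdc45 and mcm3, with 119, 117 and 103.5 CPM at 21 hpf and 0 at 28 hpf, were lower by at least 79.2-fold, 77.8-fold and 69.0-fold, and the clamp loader gene rfc4 by at least 52.8-fold. The condensin gene ncaph2 was lower by at least 63.1-fold, the histone methyltransferase gene whsc1 by at least 55.5-fold and the stress gene gadd45aa by at least 53.1-fold. Of the others, tdh was lower by at least 65.9-fold, the kinase gene rps6ka3b by at least 56.7-fold, gale by at least 54.5-fold and rbp7b by at least 52.9-fold.

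Of the key arterial genes of the roof, dll4, efnb2a, hey2 and cldn5b stayed within 2-fold between the stages and notch1b did not. Dll4 was higher at 28 hpf by 1.95-fold (1.88 to 2.02), cdh5 by 1.47-fold (1.40 to 1.55), cldn5b by 1.40-fold (1.33 to 1.49) and efnb2a by 1.201-fold (1.13 to 1.28). The gene hey2 was lower by 1.05-fold (0.987 to 1.12) and notch1b by 2.41-fold (2.19 to 2.65). Flt4 was lower by 6.61-fold (5.10 to 8.70), or 17-fold without roof cell 10 of 28 hpf, and stab2 by 1.56-fold (1.41 to 1.72), or 2.52-fold without roof cell 6. The flow gene klf2a was lower by 3.59-fold (2.43 to 5.47), or 8.81-fold without roof cell 3 of 28 hpf.

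Key blood genes of the roof differed in both directions. Lmo2 was lower at 28 hpf by 2.45-fold (2.21 to 2.72) and tal1 by 2.36-fold (2.02 to 2.77), the latter by 5.46-fold without roof cell 2 of 28 hpf. The gene myb, at 76.8 CPM at 21 hpf and 0 at 28 hpf, was lower by at least 51.2-fold, by at least 21.3-fold without roof cell 10 of 21 hpf and at least 33.3-fold without roof cell 7. Gata2b was higher by 7.76-fold (4.47 to 14.3), by 4.13-fold without roof cell 2 of 28 hpf and by 13-fold without roof cell 8 of 21 hpf. The ratio of gfi1aa was 4.07-fold (2.68 to 6.31) higher, 25.3-fold without roof cell 7 of 21 hpf and 2.00-fold without roof cell 5 of 28 hpf. Kita, at 8.00 against 0 CPM, was higher by at least 9.07-fold, and runx1 and itga2b had no thinned read in the roof at either stage.

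S-phase genes of the roof were lower at 28 hpf by a median of at least 27.9-fold (log2 -4.80), below all random lists and in 19 of 19 genes, or by at least 18.6-fold without roof cell 10 of 21 hpf, with pcna lower by 7.32-fold (6.30 to 8.54). Mitosis genes were lower by 1.74-fold (7.44 percentile, 7 lower and 15 within 2-fold of 22), by 2.86-fold without roof cell 9 and by 3.36-fold without roof cell 10 of 28 hpf. This median was lower by 1.05-fold without title part 2 and by 44.1-fold without title part 3 of the 28 hpf roof. Their gene mki67 was lower by 4.66-fold (4.14 to 5.27), by 8.48-fold without roof cell 9 and by 8.31-fold without roof cell 10 of 28 hpf. Sprouting genes were higher by 2.92-fold, above all random lists (10, 2 and 3 of 15), with itga1 higher by 92.7-fold (25 to 775), or 58.1-fold without roof cell 13 of 21 hpf, and mmp14b lower by 2.10-fold (1.89 to 2.34). The median of all genes with a ratio was log2 -0.339 in the roof and -0.547 in the floor, and scaling by size factors in place of totals moved it by 0.22 and 0.24.

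**Figure D4:**
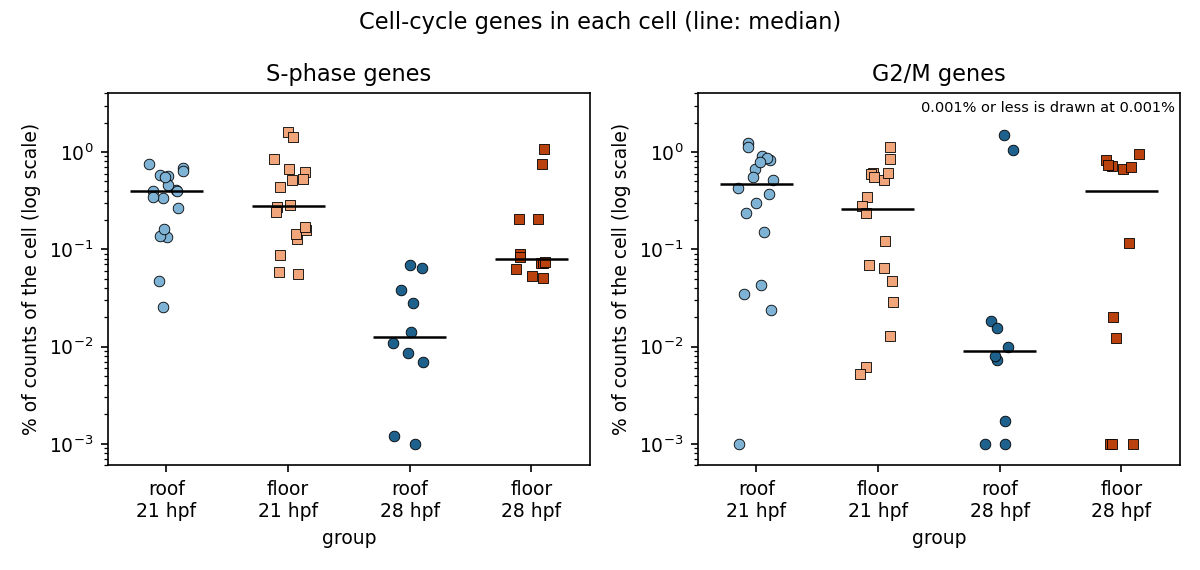
Each point is 1 cell and gives the percentage of its counts in S-phase genes (left) or mitosis genes (right) on a log axis for the 4 groups, and lines mark the medians. The S-phase medians are 0.398% and 0.280% in roof and floor at 21 hpf and 0.0124% and 0.0788% at 28 hpf.

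Arterial and Notch genes of the roof were higher at 28 hpf by a median of 1.25-fold (log2 0.32), above 98.1% of the random lists, with 7 higher, 5 lower and 15 within 2-fold of 27. The hemogenic median was lower by 1.23-fold (log2 -0.30, 50.2 percentile, 7, 7 and 4 of 18), with dnmt3bb.1 higher by 5.78-fold (4.95 to 6.77), or 10.9-fold without roof cell 10 of 21 hpf. Pan-endothelial genes were lower by 1.01-fold (81.5 percentile, 5, 4 and 11 of 20), with robo4 higher by 9.02-fold (7.38 to 11.1), she lower by 5.47-fold (5.09 to 5.89) and etv2 lower by 3.81-fold (3.53 to 4.11). The venous median was lower by 1.27-fold (45.1 percentile, 2, 4 and 5 of 11), with dab2 higher by 1.66-fold (1.52 to 1.81). Early-response and stress genes were higher by 1.67-fold (99.9 percentile, 9, 6 and 7 of 22), with gadd45ba higher by 3.39-fold (3.05 to 3.78). Flow-responsive genes were higher by 1.63-fold (98.5 percentile, 2, 2 and 6 of 10), with tek higher by 3.32-fold (2.91 to 3.79) and cav1 lower by 4.57-fold (3.63 to 5.80).

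Lists nearer to the random lists in the roof were the BMP targets, higher by 1.19-fold (84.4 percentile) but lower by 1.57-fold without roof cell 10 of 28 hpf, with id1 at 1.37-fold (1.31 to 1.43), and the Hedgehog targets, higher by 1.34-fold (75.3 percentile). Transition and adhesion genes were lower by 1.498-fold (23.3 percentile), and tgfb1a by 4.93-fold (3.70 to 6.68). Inflammatory genes were lower by 1.01-fold (70.9 percentile), although il6st was higher by 8.22-fold (5.75 to 12.1). Glycolysis genes were higher by 1.13-fold (89.7 percentile), with gapdhs higher by 7.35-fold (6.65 to 8.14) and hk1 lower by 4.74-fold (3.74 to 6.07).

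Few genes of other cell types were measured in the roof. The erythroid, myeloid, neural, notochord and sclerotome, mural and endoderm medians were lower at 28 hpf by at least 2.86-fold, 1.82-fold, 1.96-fold, 1.29-fold, 10.8-fold and 1.1-fold over 8, 4, 3, 6, 3 and 2 genes. Of the 8 erythroid genes, 5 had 0 reads at 28 hpf and low levels at 21 hpf, at most 7.65 CPM (hbbe3). By 2-fold, 2 of the 8 were higher and 6 lower. The notochord and sclerotome median was higher by 1.36-fold, 1.26-fold and 1.28-fold without roof cell 14, 16 and 18 of 21 hpf. Muscle genes were higher by 3.58-fold over 4 genes. The keratin gene krt8, at 5310 against 1325 CPM, was higher by 4.01-fold (3.87 to 4.15), and jag2b of the pronephros list by 5.30-fold (4.07 to 6.98).

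Other choices also moved list medians of the roof by over 1.5 times. Without title part 3 of 28 hpf the log2 median was -1.70 for venous, -0.93 for BMP target, -0.03 for flow-responsive, -0.56 for erythroid and 0.34 for notochord and sclerotome genes. Without title part 2 it was 0.85 for BMP target, -4.13 for S-phase and -0.78 for erythroid genes. With raw sums it was -5.62 for S-phase, -4.75 for erythroid and -2.25 for notochord and sclerotome genes. A pseudocount gave -2.35 for erythroid genes, and a minimum of 100 reads 0.23 for notochord and sclerotome genes.

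Within the floor, sums of endothelial genes were lower at 28 than at 21 hpf, whereas hemogenic genes differed in both directions. Much of the endothelial sum of 21 hpf came from floor cells 3, 6, 16 and 18, and the median floor cell had 0.157% and 0.0940% of its counts in pan-endothelial genes at 21 and 28 hpf. The adherens junction gene cdh5 had 175 CPM (162 to 190) at 21 hpf and 0 at 28 hpf, lower by at least 140.2-fold, or at least 10.6-fold without those 4 cells. At 21 hpf the median floor cell had 6.18 CPM of it. The level of myb was higher at 28 hpf by 1.46-fold (1.38 to 1.55), at 977 (938 to 1020) against 669 (643 to 696). The prothymosin gene ptmab was higher by 7.79-fold (7.44 to 8.15), at 4832 (4740 to 4920) against 621 (595 to 647).

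Of the genes higher at 28 hpf in the floor that passed the filters, the adaptor gene grap2b stood at 129 against 0 CPM, at least 154.5-fold. The microtubule regulator gene stmn1a was higher by 10.7-fold (9.42 to 12.1), the small GTPase gene rac2 by 9.32-fold (6.57 to 13.6), the actin nucleation gene arpc1b by 7.38-fold (6.65 to 8.21) and the profilin gene pfn1 by 6.61-fold (6.30 to 6.95). Csnk2b, ugdh and triobpa were higher by 8.22-fold (6.92 to 9.82), 8.08-fold (5.64 to 11.9) and 7.29-fold (5.88 to 9.13). For rnf145a, rmdn1 and senp3b the ratios were 7.21-fold (5.45 to 9.66), 6.88-fold (4.73 to 10.3) and 6.18-fold (4.39 to 8.88).

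Genes lower at 28 hpf in the floor that passed the filters included the scavenger receptor gene colec12, by at least 146-fold, and the transcription factor gene klf7b, by at least 123-fold. The gene tmem108 was lower by 67.6-fold (22.9 to 329). The collagen gene col8a2 was lower by at least 65.8-fold, gdap2 by at least 60.2-fold, the myosin gene myo7aa by at least 54.7-fold, bmp3 by at least 52.7-fold and the transporter gene slc22a7b.1 by at least 50.7-fold. For the mechanosensitive channel gene piezo1 the bound was 50-fold, for nr6a1b 48.7-fold and for the Wnt receptor ligase gene znrf3 48.2-fold. Without the 4 floor cells of 21 hpf with a roof-like pan-endothelial share, colec12 was lower by at least 36-fold, klf7b by at least 10.6-fold, tmem108 by 24.6-fold, col8a2 by at least 11.1-fold, slc22a7b.1 by at least 7.15-fold, piezo1 by at least 31.4-fold and nr6a1b by at least 21.4-fold.

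Sums of most key endothelial genes of the floor were lower at 28 hpf. Without the 4 floor cells of 21 hpf with a roof-like pan-endothelial share, however, kdrl and efnb2a were higher at 28 hpf, by 1.48-fold and 1.42-fold. Dll4 was then lower by 1.81-fold, notch1b by 2.25-fold and stab2 by 1.79-fold, and reads of cldn5b and flt4 were too few for a ratio. Floor cell 1 of 28 hpf had 1692 CPM of kdrl, and floor cell 3 had 156 CPM of efnb2a. The median floor cell of 28 hpf had 20.85 and 0 CPM of these genes. Leaving out these cells of 28 hpf as well was not tried. In the full sums, kdrl was lower by 7.77-fold (7.19 to 8.42), by 3.51-fold without floor cell 6 of 21 hpf and by 13.8-fold without floor cell 1 of 28 hpf. Dll4 was lower by 6.098-fold (5.06 to 7.41), by 11.6-fold without floor cell 1 of 28 hpf and by 3.59-fold without floor cell 3 of 21 hpf. The ratio of notch1b was 13.8-fold (10.5 to 18.4), 34.04-fold without floor cell 7 of 28 hpf and 7.23-fold without floor cell 16 of 21 hpf. Efnb2a was lower by 10.3-fold (7.65 to 14.3), or 21.3-fold without floor cell 3 of 28 hpf, and stab2 by 5.70-fold (4.30 to 7.68), or 11.1-fold without floor cell 6 of 28 hpf. Cldn5b and flt4 were lower by at least 220-fold and at least 39.1-fold, and by at least 74.4-fold and 15.3-fold without floor cell 3 of 21 hpf. The ratio of hey2 was 1.16-fold (1.06 to 1.27) higher and 4.05-fold lower without floor cell 4 of 28 hpf. No read of klf2a was counted in the floor at either stage.

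Of the key blood genes of the floor with a ratio, gata2b differed by over 2-fold in the full sums. Tal1 was lower at 28 hpf by 1.15-fold (1.06 to 1.25), and lmo2 was higher by 1.03-fold (0.964 to 1.095). Gfi1aa was lower by 1.22-fold (1.15 to 1.31), or 2.09-fold without floor cell 9 of 28 hpf, and gata2b was higher by 3.32-fold (2.40 to 4.64), or 1.72-fold without that cell. The ratio of runx1 was 1.59-fold (0.772 to 3.28) higher, or 3.64-fold without floor cell 5 of 21 hpf. Reads were too few for a ratio of kita, with 0 and 2, or of itga2b, with 5 and 3 at 28 and 21 hpf.

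As a list, hemogenic genes of the floor were higher at 28 hpf by a median of 1.01-fold (log2 0.02, 73.0 percentile), with 7 higher, 7 lower and 11 within 2-fold of 25. The core binding factor gene cbfb was higher by 3.34-fold (2.59 to 4.35), or 1.97-fold without floor cell 3 of 28 hpf, and nfe2 was lower by 10.1-fold (5.74 to 19.2), or 39.9-fold without floor cell 5. Arterial and Notch genes were lower by a median of at least 13.2-fold (log2 -3.73), below all random lists, with 4 higher, 20 lower and 2 within 2-fold of 26, or by 7.98-fold without floor cell 16 and 7.99-fold without floor cell 18 of 21 hpf. Here her9 was higher by 3.58-fold (3.22 to 3.99), or 1.86-fold without floor cell 8 of 28 hpf. The pan-endothelial median was lower by at least 27.4-fold, below all random lists (17 lower and 3 within 2-fold of 20), although fli1a stood at 1.01-fold (0.952 to 1.08). Without the 4 floor cells of 21 hpf with a roof-like pan-endothelial share, the arterial and Notch median was lower by 1.18-fold and the pan-endothelial median by 3.71-fold.

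Further lists lower at 28 hpf in the floor were the venous list by 5.70-fold (0.73 percentile, 1, 8 and 2 of 11), the sprouting list by 6.098-fold (0.51 percentile, 1, 12 and 2 of 15) and the Hedgehog targets by at least 11.8-fold over 3 genes (2.57 percentile). The venous median was lower by 11-fold, 10.9-fold and 9.47-fold without floor cell 6, 9 and 11 of 28 hpf. The sprouting median was lower by 9.21-fold without floor cell 1 or 4 of 28 hpf and by 3.59-fold without floor cell 3 of 21 hpf. Without the 4 floor cells of 21 hpf with a roof-like pan-endothelial share, the venous median was lower by 1.94-fold and the sprouting median by 1.21-fold. Transition and adhesion genes were lower by at least 3.36-fold (5.6 percentile, 11 lower and 3 within 2-fold of 14), with zeb2a at 1.01-fold (0.859 to 1.18). S-phase genes were lower by 2.08-fold (0.26 percentile, 10 lower and 9 within 2-fold of 19), or 3.17-fold without floor cell 11 of 28 hpf, with mcm4 lower by 1.14-fold (1.04 to 1.25), or 1.99-fold without floor cell 6 of 28 hpf. Flow-responsive genes were lower by 1.60-fold (47.6 percentile, 1, 4 and 4 of 9), by 2.45-fold without floor cell 5 and by 2.98-fold without floor cell 7 of 28 hpf.

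Glycolysis genes of the floor were higher at 28 hpf by 2.41-fold, above all random lists (11, 4 and 3 of 18), but by 1.31-fold without floor cell 6 of 28 hpf and by log2 0.00 without the cells of over 1% erythroid or muscle counts. Its gene hk1 was lower by 2.12-fold (1.79 to 2.54). BMP targets were higher by 1.301-fold (92.8 percentile, 4, 3 and 2 of 9), by 3.31-fold without floor cell 16 of 21 hpf, by 3.46-fold without the 4 floor cells of roof-like pan-endothelial share, and lower by 1.31-fold without floor cell 1 of 28 hpf, with id3 higher by 4.04-fold (3.54 to 4.62). Mitosis genes were higher by 1.28-fold (90.6 percentile, 7, 1 and 14 of 22), with ube2c and birc5a higher by 3.19-fold (2.71 to 3.75) and 3.04-fold (2.47 to 3.77). Inflammatory genes were lower by 1.40-fold (52.8 percentile, 3, 8 and 6 of 17), with stat1a higher by 3.53-fold (2.75 to 4.57). Early-response and stress genes were lower by 1.197-fold (47.3 percentile, 6, 8 and 9 of 23), with btg2 higher by 2.09-fold (1.85 to 2.35) and hspa5 lower by 4.94-fold (4.61 to 5.31).

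Erythroid genes of the floor were lower at 28 hpf by 1.55-fold (0.58 percentile, 1, 8 and 12 of 21), or 3.07-fold without floor cell 11 of 28 hpf, with alas2 lower by 3.59-fold (3.24 to 3.98). With 1 cell left out at a time, the erythroid log2 median ranged from -1.616 to -0.057. Myeloid genes were higher by 1.03-fold over 6 genes, or 1.65-fold without floor cell 8 of 21 hpf, with cebpa at 1.01-fold (0.945 to 1.09). The muscle median was higher by at least 285-fold over 16 genes, and was log2 -2.10 without floor cell 6 of 28 hpf. Epidermis genes were higher by at least 11.5-fold over 5 genes, or at least 6.14-fold without floor cell 8 of 28 hpf, whereas krt8 was lower by 8.47-fold (7.40 to 9.73), by 41.5-fold without floor cell 1 of 28 hpf and by 3.08-fold without floor cell 3 of 21 hpf. The neural, notochord and sclerotome, pronephros, mural and endoderm medians were lower by at least 8.00-fold, at least 26.4-fold, 8.77-fold, at least 1.13-fold and at least 3.99-fold over 5, 1, 2, 2 and 2 genes. The neural median was lower by at least 4.70-fold without floor cell 3 of 21 hpf and by at least 4.86-fold without the 4 floor cells of roof-like pan-endothelial share.

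Other choices moved list medians of the floor by over 1.5 times. Without the cells of over 1% erythroid or muscle counts the log2 median was -3.88 for venous, -3.66 for sprouting, -1.55 for flow-responsive, -2.68 for transition and adhesion, -1.99 for S-phase, 1.21 for mitosis, -2.49 for muscle and -3.59 for neural genes, and the BMP target median was -0.04. A minimum of 100 reads gave -2.61 for arterial and Notch, -3.57 for venous, -5.48 for pan-endothelial, 0.996 for BMP target, -2.07 for flow-responsive, -5.84 for neural and -3.08 for epidermis genes. With raw sums it was -6.99 for pan-endothelial, -1.42 for erythroid, 10.02 for muscle, -7.51 for neural and 6.72 for epidermis genes. Without title part M12 of 28 hpf the values were -3.02 for arterial and Notch, -1.69 for flow-responsive, -0.90 for transition and adhesion, 1.97 for glycolysis, -1.59 for erythroid, 9.16 for muscle and -2 for neural genes. Without M8 they were -1.15 for BMP target and -0.82 for myeloid genes, and without M9 4.11 for epidermis genes. Another seed gave -3.32 for sprouting and -1.70 for flow-responsive genes, and mean per-cell levels gave -2.01 for flow-responsive genes. A pseudocount gave -3.01 for arterial and Notch genes, and leaving out cells with under 2000 genes gave -3.44 for venous genes. As title forms differed between 21 and 28 hpf, stage and collection series cannot be told apart in either region.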

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

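The tests of technical explanations given in this part were chosen only after the results were seen. In the group of 10 cells, the roof at 28 hpf, a gap test asked whether the most extreme cell stood apart from the others, and chance flags about 1 in 20 groups of normally spread values. A measure at 0 in all cells but 1 is always flagged, so that rate does not hold for such measures, mcm5 and actc1b among them. Of 34 measures tested, 10 were flagged.

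Roof cell 2 of 28 hpf stood apart in 4 measures. It had 588.5 CPM of tal1 where the other cells had 0 to 125.5, and 235.2 of gata2b where the others had 0 to 91.72. Its myeloid genes took 0.054% of counts, against 0.005% to 0.0308%, and it had 195.3 CPM of actc1b where the others had 0. In roof cell 5, gfi1aa reached 219.8 CPM (others 0 to 115.1). Roof cell 6 had 3286 CPM of cldn5b (others 156.1 to 1826) and 1190 of stab2 (others 0 to 348.6). In roof cell 8, runx1 stood at 8.955 CPM (others 0 to 2.643) and mcm5 at 40.77 (others 0), and in roof cell 10, pcna stood at 469.3 (others 0 to 204.3). The sprouting and tip-cell list was also marked because its stage ratio was of opposite sign in the regions, with a log2 median of -2.608 in the floor and 1.545 in the roof. The difference between these values was not tested.

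Erythroid genes were high in floor cells while endothelial genes were low. Roof-like endothelial cells that took up free blood cell RNA would keep their endothelial genes. The pan-endothelial median was -2.145 at 21 hpf and -7.411 at 28 hpf, so such uptake alone does not account for the low endothelial genes. As these low levels are part of the pattern and were seen beforehand, they are no separate test. An endothelial cell and a blood cell picked together at 28 hpf would still carry endothelial genes. The genes cdh5, clec14a and flt1 were lower in the floor by at least 767-fold to 1147-fold. They are among the genes named above for their low floor levels, so they alone cannot decide this. Over the whole pan-endothelial list, with fli1a at log2 -0.89, the median of -7.411 had an order interval over its genes up to -5.346. For the sum of the 12 floor cells, this argues against such a pair if the endothelial cell gave 1 in 10 or more of the RNA. It does not rule out such a pair in single cells, as the floor cells of 28 hpf were not split by erythroid counts. At 21 hpf such a pair would keep endothelial genes within 10-fold of the roof if the endothelial cell gave 1 in 10 or more of the RNA. In the sum of the 8 floor cells of over 1% erythroid counts the pan-endothelial median was -6.379. Its order interval over the genes reached up to -4.173, which argues against such a pair for this sum. In the sum of the 6 others with erythroid counts above the roof the median was -5.145. Its order interval reached up to -2.716, and the explanations cannot be told apart. Blood cells with no activity of the kdrl promoter, picked in place of endothelium, would lack kdrl reads. Whether the picking of red Eos+ cells left such cells out was not tested. Of 30 floor cells 26 had 5 or more unthinned kdrl reads, but 14 of 18 and 5 of 12 had 5 or more thinned ones, and a few reads do not show promoter activity, so the explanations cannot be told apart. A difference in fate between the floor and the roof stays open as untested, and the 21 erythroid genes lie in no other list, with hbbe3 at 2806 CPM and hbae1.3 at 2679 in the floor at 21 hpf and hbbe1.1 at 3286 at 28 hpf.

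Muscle genes were high in floor cell 6 of 28 hpf, at 36220 CPM of actc1b and 9619 of mylpfa. In that cell 15 of 16 contractile and metabolic muscle genes had 5 or more thinned reads and myod1 and myog had 0. As the cell was singled out by its muscle genes, RNA of muscle fibres carried along with it cannot be told apart from other sources. Muscle genes as a feature of the floor at 28 hpf are argued against by the other 11 floor cells, in which at most 1 of those genes was detected. Whether the picking of red Eos+ cells would remove a whole muscle fibre was not tested, and 21 muscle genes lie in no other list.

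S-phase genes were low in the roof at 28 hpf. A general loss of low transcripts in the 28 hpf roof libraries would lower matched random lists as far. Their central 95% began at -1.031, where the S-phase median was -4.8, so such a loss alone does not account for it. The S-phase list had already been seen to lie below all random lists, so this is no separate test. No 1 title part of the 28 hpf roof carried the low median, which was -4.126 to -5.282 with 1 title part left out. The titles do not say what these parts stand for, so a collection series as the source cannot be told apart. A difference between the 21 hpf and the 28 hpf collection cannot be told apart from a stage difference, since 0 title parts hold cells of both stages. Fewer dividing cells in the roof at 28 hpf stays open as untested.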

How the results depend on the processing

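The removal of 12 cells with over 1% erythroid or muscle counts was chosen only after the result was seen. Under the alternatives that left out no cells, the hemogenic median ranged from 1.15 (minimum of 100 reads) to 2.698 (raw sums) for the regions at 21 hpf and from 1.341 to 2.16 at 28 hpf, and the arterial and Notch median from -1.829 to -1.46 and from -6.146 to -4.385. Without those 12 cells the hemogenic medians were 2.381 and 1.433 and the arterial and Notch medians -0.7763 and -5.846. The arterial and Notch median of the floor, 28 against 21 hpf, was then -4.125 in place of -3.725, and the cause was not tested. With 1 cell left out at a time, the hemogenic median ranged from 1.246 to 2.052 for the regions at 21 hpf, 1.84 to 2.11 at 28 hpf, -0.636 to 0.040 for the stages in the roof and -0.270 to 0.192 in the floor. The arterial and Notch median ranged from -1.809 to -1.443, -5.733 to -4.407, 0.174 to 0.389 and -3.808 to -2.997. The 4 floor cells of 21 hpf with a roof-like pan-endothelial share were also left out after the result was seen. Without them the arterial and Notch median was -4.043 for the regions at 21 hpf and -0.2387 for the stages in the floor. For the stages, this shows that the median rested largely on these cells. Kdrl and efnb2a reversed to 0.564 and 0.5048 for those stages. In the floor at 28 hpf, cell 1 had the highest kdrl and cell 3 the highest efnb2a. The reversals were not tried without cells 1 and 3. The muscle list reversed for the regions at 28 hpf, to -2.951 without those 12 cells and -3.411 without M11, whose only cell is floor cell 6, with a range of -3.411 to 7.402. For the stages in the floor it was -2.485 and -2.097, with a range of -2.097 to 8.28, which shows that 1 cell carried it. With a minimum of 100 reads, the epidermis list reversed to -5.792 for the regions at 28 hpf and -3.082 for the stages in the floor, as only krt8 had that many reads. Raw sums moved 14 of 67 list results and 36 of 155 gene results out of their intervals, and they moved the median of all genes by -0.119 for the regions at 28 hpf and 0.101 for the stages in the roof. Without the 12 cells of over 1% erythroid or muscle counts, 74 gene results moved and 40 did not. Without the 4 floor cells of roof-like pan-endothelial share, 33 gene results moved, 2 reversed and 40 did neither. At 200000 reads per cell, a gene with 0 reads is only known to lie below 3 reads per sum. No paired analysis was possible because the numbers at 21 hpf name single cells, no title part is shared by the groups compared at 28 hpf or between the stages, and no test across cells was made.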

Other observations

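The cells named here were chosen after their values were seen. Among the 18 floor cells of 21 hpf, cells 3, 6, 16 and 18 had pan-endothelial shares of 1.60%, 3.69%, 1.93% and 0.845% and erythroid shares of 0.006%, 0.0146%, 0.0085% and 0.008%. Their myb levels were 0.874, 0, 0.577 and 2.27 CPM. Roof cells 7 and 10 of 21 hpf had 483 and 821 CPM of myb. In the roof at 28 hpf, cells 9 and 10 had 1.05% and 1.51% of their counts in mitosis genes.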
